A study of Mus musculus with 6 samples.

How the data were processed

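RNA sequencing of tumour-associated macrophages was measured in 6 libraries, 3 in each of 2 groups. Per the labels, the macrophages were sorted as CD11b+ F4/80+ Ly6G- Ly6C- cells from mammary tumours of female MMTV-PyMT mice of the FVB/NJ strain at 65 days of age, and each library came from a separate mouse. Both groups carried loxP-flanked Atg5 alleles, and the group labelled Atg5 KO also carried LysMcre, a Cre recombinase knocked into the Lyz2 gene. Groups and replicate numbers were taken from the labels. RNA was purified with a Zymo Research kit and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols.

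The deposited table holds FPKM values, which scale reads by gene length and by the library's counted reads, for 35275 genes in 6 columns, 1 per mouse, per the file headers. STAR and CASAVA and the genome build mm10 are named in the submitters' processing notes, without versions. The counting program, its strand setting, the annotation release and any filter are not given in the sources used here. Multiplying each FPKM by the listed gene length gave a whole multiple of 1 read for 100.0% of values in every library, within a tolerance of 0.01 read. The reads recovered in this way added up to between 18770262 and 21173301 per library, so a gene of 1 kb with 1 read stood at an FPKM between 0.0472 and 0.0533. Whether a read means a single read or a read pair is not given. Reads of near-identical genes, such as Lyz1 and Lyz2, can be divided between them by the aligner or counter, so the values of such genes are less certain. Overlapping and antisense genes carry the same uncertainty.

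Gene symbols and positions were taken from the table. Of its gene identifiers, 97.77% were in GENCODE release M21, which uses the same build, and 99.88% of those overlapped the position given there. Exon positions of Atg5 came from that release. FPKM was computed over the whole gene, so no value isolates a single exon.

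The main test was fixed before the data were examined. Values were transformed to log2(FPKM + 1), genes with a mean FPKM of at least 1 over the 6 libraries were kept, and a linear model with the group as its only term was fitted in limma 3.58.1 under R 4.3.3 with the mean-variance trend in the empirical Bayes step (limma-trend). Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are differences of mean log2(FPKM + 1), labelled Atg5 KO minus labelled Atg5 WT, and understate the change of low genes. Single values, such as a score per library, were compared by an exact two-sided permutation test, whose smallest possible p is 0.1 with 3 libraries against 3. Means are given ± SD over 3 libraries unless SE is written.

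A total of 34 gene lists covering pathways, cell types and RNA quality were also fixed before the data were examined, and 31 of them had at least 5 genes past the filter. They were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with the correlation estimated from the libraries. Of 733 list entries, 722 matched a symbol of the table, 9 a current symbol, 1 an older symbol and 1 none. The mean log2(FPKM + 1) of the mammary epithelium and tumour cell list and of the macrophage identity list served as the tumour-cell score and the macrophage score of each library.

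The genes named were chosen by a rule written in advance. It took Atg5 and Lyz2; up to 10 genes per direction with the largest change among those past the threshold whose groups did not overlap; with fewer than 5 such genes, the genes of smallest p with groups that did not overlap, up to 5 per direction and leaving out predicted genes and symbols on several rows; and from each list up to 4 members with the smallest p in its direction if the list was called, otherwise up to 2 for a pathway and 1 for a cell type or quality list. Genes named outside that rule are said to be so, and a few genes that the rule names are not reported here.

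The fits were tested on simulated data before use. With reads drawn for 12274 genes at the spread measured between these libraries, limma-trend called 25.3% of genes changed by a log2 of 1 and 80.4% of genes changed by a log2 of 3, with 2 unchanged genes called. With that spread divided by 4 and 12296 genes, the shares were 92.9% and 100%, with 23 unchanged genes called. A list raised by a log2 of 1 was called by camera in 20 of 20 draws and 0 of 521 tests of unshifted lists were, but the simulated genes varied independently, which genes of the real libraries did not. The same limit holds for the shares of genes called. At the measured spread they came from data with 99 and 92 changed genes, and they need not hold in the real libraries.

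Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter on low values, a filter at a mean FPKM of 5, median-ratio scaling, quantile normalization, robust empirical Bayes, library weights, a log2 fold limit of 1, the estimated correlation, a block for the replicate number and leaving out each library in turn. Alternatives chosen after seeing the data were the tumour-cell score as a covariate, limma-voom on the recovered reads, leaving out the 3 libraries with the most tumour-cell RNA and the macrophage list without Lyz2. The main test was also repeated on the 10 splits of the 6 libraries into 3 and 3. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.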

Results

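Gene expression was measured by RNA sequencing in macrophages sorted from spontaneous mammary tumours of MMTV-PyMT mice, in which the polyoma middle T oncogene drives tumours of the mammary epithelium. The comparison asked how macrophage gene expression differs when Atg5, which encodes a protein needed for autophagosome formation, is targeted for deletion in myeloid cells by LysMcre. It set 3 mice labelled Atg5 KO against 3 mice labelled Atg5 WT. The recovered reads numbered 19069025, 19302509 and 18770262 in the libraries labelled Atg5 WT and 21173301, 20734298 and 19906483 in those labelled Atg5 KO. Values of 12332 genes passed the filter and were tested.

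Atg5 itself (chromosome 10, 44268358 to 44364291, mm10) went against the label at the level of the whole gene. Its FPKM was 5.18 ± 0.0875 in the libraries labelled Atg5 WT (5.15, 5.11 and 5.28) and 16.0 ± 1.77 in those labelled Atg5 KO (14.0, 16.6 and 17.4), a 3.09-fold higher mean. The recovered reads were 231, 232 and 233 against 698, 808 and 815. The difference was 1.45 on the log2 scale with an SE of 0.11, the groups did not overlap, and it did not pass over all genes (limma-trend adjusted p = 0.103; exact permutation p = 0.1, the smallest possible). Without the library labelled Atg5 WT replicate 2 the adjusted p was 0.0472. The FPKM covers all 8 exons of the 2352 bp gene model, in which exon lengths run from 79 to 1376 bp. A loss of any internal exon removes a small part of it, 5.44% for exon 3 (44289863 to 44289990, 128 bp), and which exon is flanked by loxP sites is not given in the sources used here. The gene-level value therefore checks nothing about the deleted part. Directions below follow the labels, which gene-level Atg5 goes against and Lyz2, at the Cre locus, goes with.

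Lyz2 (chromosome 10, 117277334 to 117282274), which encodes the macrophage lysozyme and carries the Cre of LysMcre, was the gene that passed the test. Its FPKM was 4446 ± 2267 in the libraries labelled Atg5 WT and 12.1 ± 3.85 in those labelled Atg5 KO, 367-fold lower, with 0.273% of the mean left. The log2 difference was -8.29 with an SE of 0.47 (limma-trend adjusted p = 0.0306), in the direction that the labels give for a knock-in at this locus. The neighbouring paralog Lyz1 (117287796 to 117292868), the Paneth cell lysozyme gene, went the other way. It stood at 176 ± 70.6 in the libraries labelled Atg5 WT and 1504 ± 285 in those labelled Atg5 KO, 8.55-fold higher, and did not pass over all genes (log2 difference 3.16, SE 0.35, limma-trend adjusted p = 0.372). Lyz1 and Lyz2 are close in sequence, so reads may be divided between them. Leaving out the library labelled Atg5 WT replicate 1 or 3, or Atg5 KO replicate 1, 2 or 3, raised the adjusted p of Lyz2 to 0.37, 0.0622, 0.284, 0.0888 and 0.312. Without Atg5 WT replicate 2 the adjusted p of Lyz1 was 0.0316.

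**Figure D1:**
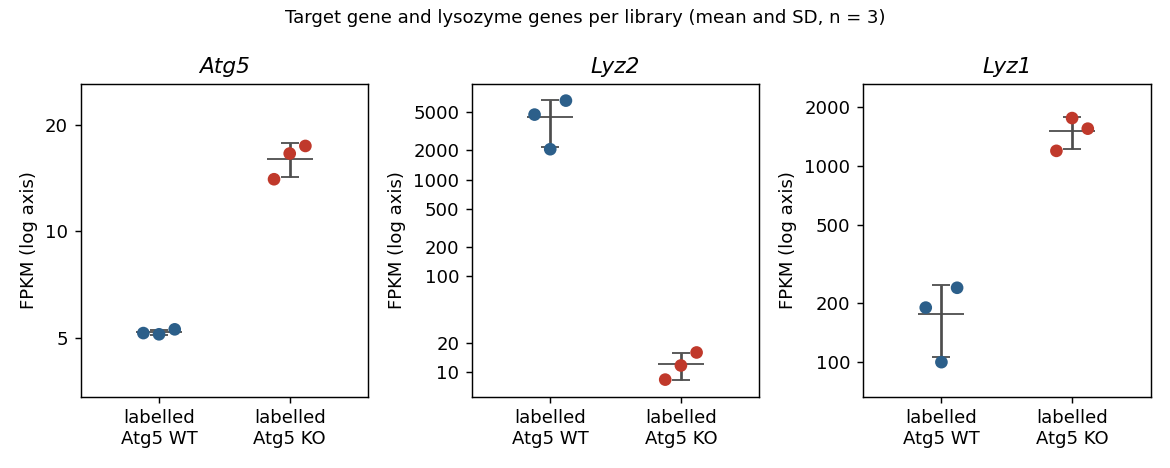
FPKM of Atg5, Lyz2 and Lyz1 in each library on a log axis; points are libraries, and bars are the mean and SD of 3 libraries per label. Atg5 and Lyz1 are higher and Lyz2 is lower in every library labelled Atg5 KO than in every library labelled Atg5 WT, with means of 16.0 against 5.18, 1504 against 176 and 12.1 against 4446.

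Beyond Lyz2, no gene was called at this number of mice. limma-trend found 0 genes higher and 1 lower in the libraries labelled Atg5 KO, limma-voom on the recovered reads found the same numbers, and without Atg5 WT replicate 2 the counts were 2 and 16. At an unadjusted p under 0.05 there were 597 higher and 638 lower genes, against 617 expected in all with no change. The groups did not overlap for 18.6% of genes, 1134 higher and 1161 lower, where chance gives 10%. After Atg5 and Lyz1, and passing over predicted genes, the higher genes of smallest p whose groups did not overlap were Rnase6, a secreted antimicrobial ribonuclease (FPKM 4.46 ± 0.98 against 11.7 ± 2.12), Ypel3 (52.0 ± 4.5 against 84.9 ± 6.97) and Batf3, a transcription factor of dendritic cells (15.3 ± 2.32 against 27.7 ± 2.19), giving the libraries labelled Atg5 WT first. None of these passed. The lower genes chosen in the same way, which did not pass either, were Erdr1 (171 ± 7.94 against 98.2 ± 1.61), Il23a, which encodes a subunit of interleukin 23 (7.98 ± 0.637 against 3.66 ± 0.815), Prol1 (12.1 ± 3.48 against 1.43 ± 1.23) and the immunoglobulin segment Igkv10-96 (10.8 ± 7.53 against 0.601 ± 0.304). Their limma-trend adjusted p was 0.372 for Erdr1 and 0.492 for the others. Of the 31 fixed gene lists tested, camera called 18 at the preset correlation, 10 higher and 8 lower, and 0 with an estimated correlation (smallest adjusted p = 0.503). Other splits of the 6 libraries into 3 and 3 gave up to 21 called lists.

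Transcripts of mammary epithelium and tumour cell markers were present in every library in unequal amounts, although the cells were sorted on CD11b and F4/80. Krt8 and Epcam are named here outside the rule. Keratin gene Krt8 had an FPKM of 474, 798 and 108 in the libraries labelled Atg5 WT and 302, 105 and 49.0 in those labelled Atg5 KO. Epcam, an epithelial adhesion molecule, had 247, 446 and 52.0 against 160, 56.1 and 30.2. The tumour-cell score was 5.995 ± 1.61 against 4.81 ± 0.977 (exact permutation p = 0.3, smallest possible 0.1) and the macrophage score, which includes Lyz2, 7.78 ± 0.878 against 8.03 ± 0.182 (exact permutation p = 0.9). Lyz2 lowers that score in the libraries labelled Atg5 KO; without Lyz2 it was 7.53 ± 0.88 against 8.28 ± 0.168, higher by 0.75 (exact permutation p = 0.3). The library labelled Atg5 WT replicate 2 stood apart, with the highest tumour-cell score of 7.37 and the lowest macrophage score of 6.80, and the first principal component held 74.99% of the variance. All 23 members of the mammary epithelium and tumour cell list, led by Krt14, Krt5, Krt7 and Cldn4, had a lower mean in the libraries labelled Atg5 KO. The median log2 difference was -1.27. The members whose groups did not overlap numbered 0, as did those past the gene test over all genes or adjusted over the list alone. camera called the list (adjusted p = 0.00417), but not with an estimated correlation (adjusted p = 0.727), nor without Atg5 WT replicate 2 (median -0.49, adjusted p = 0.107), and without Atg5 WT replicate 3 the median was -2.16.

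**Figure D2:**
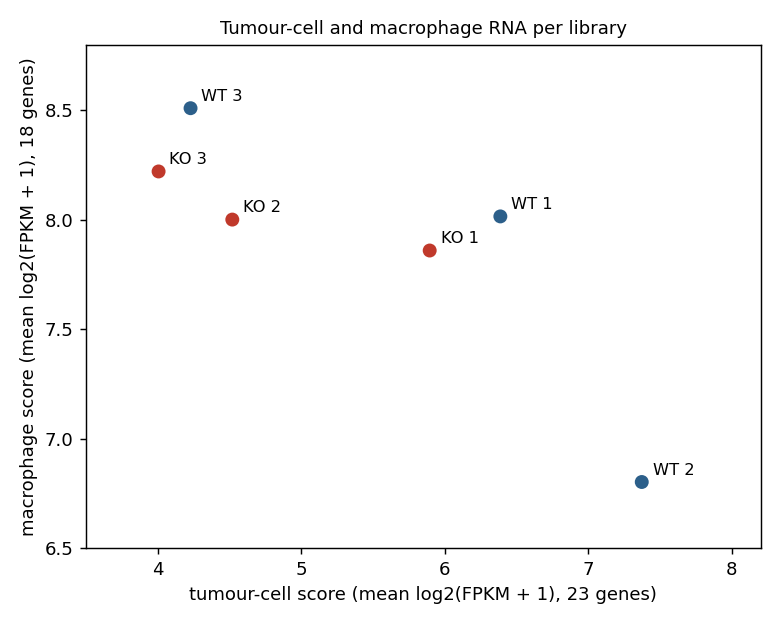
Tumour-cell score (x axis) and macrophage score (y axis) of each library, both mean log2(FPKM + 1) of a fixed list, in blue for libraries labelled Atg5 WT and red for Atg5 KO. Atg5 WT replicate 2 lies apart at 7.37 and 6.80, and the other 5 libraries lie between 4.004 and 6.39 on the tumour-cell score.

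The lists of fibroblasts and pericytes, of endothelial cells, and of mast cells and eosinophils also had negative medians in the libraries labelled Atg5 KO. That direction is taken from labels that gene-level Atg5 goes against and Lyz2 goes with. All 16 fibroblast and pericyte genes were lower, with a median log2 difference of -1.73. For 14 of them the groups did not overlap, including Sparc (FPKM 214 ± 153 against 46.6 ± 18.8), Acta2, Pdgfrb and Tagln. All 13 endothelial genes were lower, with a median of -1.18, led by the vascular receptor Kdr (3.71 ± 1.33 against 1.02 ± 0.433), Cldn5, Cdh5 and Esam. The mast cell and eosinophil list had a median of -1.48 over 6 genes, with the mast cell proteases Cma1, Mcpt4, Tpsb2 and Cpa3 lower and 2 members higher. No member passed over all genes; adjusted over the list alone, 0 fibroblast, 11 endothelial and 4 mast cell genes did. camera called the fibroblast, endothelial and mast cell lists at the preset correlation (adjusted p = 2.29e-07, 2.29e-07 and 0.0418), and none with an estimated correlation (adjusted p = 0.503 for each). With the tumour-cell score as a covariate the fibroblast and endothelial medians were -1.01 and -0.71, and without Atg5 WT replicate 2 they were -1.08 and -0.86. The mast cell call was lost without Atg5 WT replicate 3 (median -1.76, adjusted p = 0.259) and without Atg5 KO replicate 1 (median -1.43, adjusted p = 0.142). It was also lost with no filter, where the median shrank to -0.12 (adjusted p = 0.19), with limma-voom (median -2.00, adjusted p = 0.0644) and with library weights, whose estimation did not converge (median -1.29, adjusted p = 0.16).

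Genes induced by interferon gamma, the cytokine that activates macrophages, were higher in the libraries labelled Atg5 KO. Of 22 measured members 21 were higher, with a median log2 difference of 1.51 against -0.09 for all tested genes, and for 15 the groups did not overlap. Guanylate-binding proteins Gbp5 (FPKM 4.46 ± 1.61 against 30.1 ± 16.1) and Gbp2 (16.1 ± 1.56 against 62.5 ± 28.0), the GTPase gene Tgtp2 (0.872 ± 0.247 against 12.3 ± 7.86) and the transcription factor Irf1 (71.7 ± 4.24 against 106 ± 11.8) led the list. No member passed over all genes, and 14 passed adjusted over the list alone. The mean log2(FPKM + 1) of the list was 3.07, 2.50 and 3.04 in the libraries labelled Atg5 WT and 4.59, 3.51 and 4.73 in those labelled Atg5 KO. camera called the list at the preset correlation (adjusted p = 4.23e-15), and in each fit that left out 1 library, but not with an estimated correlation (adjusted p = 0.503). The preset test also called it in 7 other splits of the 6 libraries into 3 and 3, so the call is not particular to the labels. With the tumour-cell score as a covariate, chosen after seeing the data, the median was 1.32. With that covariate and an estimated correlation camera did not call the list (adjusted p = 0.557). The list's mean less the macrophage score without Lyz2 was higher by 0.65 with an SE of 0.505 (exact permutation p = 0.3).

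Antigen presentation genes ran in the same direction, with gene-level Atg5 again against the label and Lyz2 with it. For MHC class I presentation, 16 of 19 members were higher, with a median of 0.79, among them the activator Nlrc5 (3.76 ± 1.45 against 14.3 ± 5.24), the immunoproteasome subunit Psmb9 (14.1 ± 3.94 against 42.4 ± 15.8), the peptide transporter Tap1 (14.0 ± 2.09 against 39.2 ± 15.3) and H2-Q4. For MHC class II presentation and costimulation, 14 of 16 were higher, with a median of 0.75, led by the class II activator Ciita (8.42 ± 2.23 against 28.3 ± 11.3), H2-Ob, H2-DMa and H2-Ab1. The members adjusted over the list alone numbered 12 and 0, and over all genes 0 and 0. camera called both lists (adjusted p = 7.67e-11 and 1.49e-06), but not with an estimated correlation (adjusted p = 0.503 for each). The class II median was 0.41 without Atg5 WT replicate 2 and 0.40 with the tumour-cell score as a covariate, and without the 3 libraries with the most tumour-cell RNA it was 0.27 and not called (adjusted p = 0.213). That fit leaves 1 library labelled Atg5 WT against 2 labelled Atg5 KO and 1 residual degree of freedom. The type I interferon list overlapped these in no gene and had a smaller median of 0.26, with 27 of 35 members higher, among them Oas2, Parp14 and Stat2. Its call (camera adjusted p = 1.23e-04) was lost with an estimated correlation (adjusted p = 0.566) and without Atg5 WT replicate 2 (median 0.13, adjusted p = 0.15), and its median was 0.52 without Atg5 KO replicate 2 and 0.15 without Atg5 KO replicate 1 or 3.

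**Figure D3:**
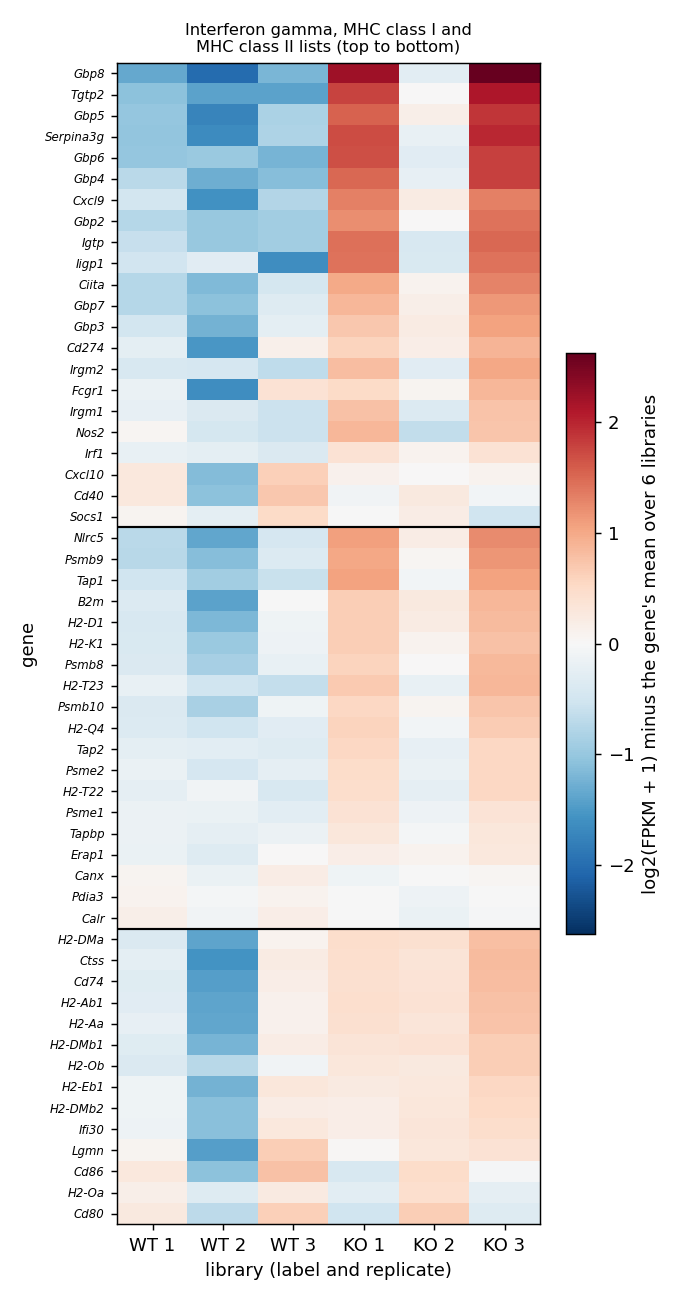
log2(FPKM + 1) of each of 55 genes in each library, minus the gene's mean over 6 libraries (red above, blue below), for the interferon gamma, MHC class I and MHC class II lists from top to bottom; a gene of several lists is drawn once. The interferon gamma genes stand highest in Atg5 KO replicates 1 and 3, with list means of 4.59 and 4.73, and lower in replicate 2 at 3.51.

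Lists of macrophage function were higher in the libraries labelled Atg5 KO, which also had the lower mean tumour-cell score (4.81 against 5.995). The macrophage identity list had a median of 0.79 over 18 genes and a mean of 0.25, since it contains Lyz2, and 16 members were higher, led by Maf, Mertk, Aif1 and Cx3cr1. The lysosome and TFEB target list had a median of 0.42, with 31 of 36 higher, including Psap, which encodes the saposin precursor (2239 ± 769 against 4115 ± 691), the lysosomal acid lipase gene Lipa (110 ± 1.79 against 137 ± 3.28), Tfeb and Scarb2. Phagocytic and efferocytic receptors had a median of 0.61, led by the scavenger receptor Marco (3.94 ± 3.32 against 15.6 ± 5.02), Fcgr4, Mertk and Timd4. The lipid-associated list had a median of 0.45 with 20 of 26 higher, led by Lipa, Lpl, Apoc2 and Abcg1. All 7 NADPH oxidase genes were higher, with a median of 0.77, among them Cybb, Cyba, Ncf1 and Rac2. NRF2 targets went both ways, 12 higher and 10 lower, with a median of 0.07, and the higher ones included Blvrb and G6pdx.

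camera called these 6 lists at the preset correlation (adjusted p = 6.35e-05 for macrophage identity, 3.99e-08 for lysosome, 5.72e-04 for phagocytic receptors, 1.01e-04 for lipid-associated genes, 5.88e-04 for NADPH oxidase and 0.0356 for NRF2 targets). With an estimated correlation none was called (adjusted p = 0.551 for macrophage identity and 0.503 for each of the others). Over all genes the members past the test were Lyz2 alone, and adjusted over the list alone likewise. With the tumour-cell score as a covariate, the calls of macrophage identity, lipid-associated genes, phagocytic receptors, NADPH oxidase and NRF2 targets were lost (adjusted p = 0.163, 0.33, 0.271, 0.0959 and 0.271). Their medians were then 0.36, 0.15, 0.29, 0.36 and 0.07, the last of which did not fall, and the lysosome median was 0.14 (adjusted p = 0.0481). Without Atg5 WT replicate 2 the medians of macrophage identity, lysosome, phagocytic receptors, lipid-associated genes and NADPH oxidase were 0.34, 0.13, 0.29, 0.13 and 0.34, all still called at the preset correlation. Without Atg5 WT replicate 3 the phagocytic and lipid-associated medians were 0.94 and 0.74. Without the 3 libraries with the most tumour-cell RNA, which leaves 1 library labelled Atg5 WT, none of the 6 was called (lysosome median 0.04, adjusted p = 0.424). The NRF2 call was also lost without Atg5 WT replicate 2 (median 0.05, adjusted p = 0.306) or Atg5 KO replicate 2 (median 0.04, adjusted p = 0.166), and its median was 0.12 and 0.14 without Atg5 WT replicate 1 and 3. It was called in 11 of 20 alternatives, and the other losses were with a filter at a mean FPKM of 5 (adjusted p = 0.087), median-ratio scaling (median 0.20, adjusted p = 0.0799), quantile normalization (median 0.09, adjusted p = 0.277) and library weights (median 0.05, adjusted p = 0.107).

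Metabolic and growth lists had small negative medians in the libraries labelled Atg5 KO, set here beside a median of -0.09 for all tested genes. Cholesterol synthesis and SREBP2 targets had a median of -0.33, with 19 of 22 lower, among them Cyp51 (7.49 ± 0.844 against 4.35 ± 0.661), Srebf2 and Sqle. Glycolysis and hypoxia genes had a median of -0.24, with 22 of 28 lower, led by the glucose transporter Slc2a1 (74.7 ± 10.4 against 46.4 ± 8.01), Ero1l, Ndrg1 and Tpi1. The unfolded protein and integrated stress response list had a median of -0.17 with 21 of 23 lower, including Atf4, Hyou1, Sesn2 and Ddit3, and the cell cycle list -0.15 with 29 of 33 lower, including Ccnb2, Rrm1, Mcm7 and Tk1. No member of the 4 lists passed over all genes or adjusted over the list alone. camera called them at the preset correlation (adjusted p = 0.00305, 0.0178, 0.00773 and 0.00263), and not with an estimated correlation (adjusted p = 0.517 for cholesterol and 0.503 for the others). The calls for glycolysis, stress response and cell cycle were lost without Atg5 WT replicate 3 (adjusted p = 0.218, 0.224 and 0.373), with medians of -0.28, -0.14 and -0.14. The cell cycle call was lost also without Atg5 KO replicate 1 (median -0.10, adjusted p = 0.0997) and under median-ratio scaling (median -0.03, adjusted p = 0.106) and quantile normalization (median -0.02, adjusted p = 0.135). Under median-ratio scaling the stress response call was lost as well (median -0.04, adjusted p = 0.0849), and the cholesterol median was -0.20 without Atg5 WT replicate 2 and -0.13 with the tumour-cell score as a covariate.

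The autophagy machinery apart from Atg5 was not called. Its 33 genes had a median of -0.05, with 14 higher and 19 lower (camera adjusted p = 0.927); the median turned positive under median-ratio scaling and quantile normalization, and camera ranked it slightly above other genes. Ulk2, an initiating kinase, had 12.7 ± 1.81 against 16.3 ± 1.22 and Atg16l2 8.43 ± 1.76 against 6.36 ± 0.782. The 13 autophagy receptors had a median of -0.17 (adjusted p = 0.697), with Tollip at 31.9 ± 1.26 against 24.9 ± 2.85 and Fundc1 at 20.8 ± 2.03 against 24.3 ± 1.48. On leaving out any 1 library the medians ran from -0.187 to -0.0064 for the machinery and -0.208 to -0.058 for the receptors. Neither list was called in those fits. Nuclear-encoded oxidative phosphorylation genes had a median of -0.01 and a mean of -0.002 while camera pointed up (adjusted p = 0.202; Sdhb and Ndufa1 led), and under median-ratio scaling the median was 0.13 and the list was called (adjusted p = 0.00215). They were also called without Atg5 WT replicate 2 (median 0.05, adjusted p = 0.0219) and with the tumour-cell score as a covariate (median 0.07, adjusted p = 0.0162), but with an estimated correlation they were called neither with the covariate (adjusted p = 0.756) nor in the main comparison (adjusted p = 0.809). Leaving out the 3 libraries with the most tumour-cell RNA gave a median of 0.09 (adjusted p = 0.0231), from 1 library labelled Atg5 WT and not taken as a call. The 12 mitochondrially encoded genes had a median of -0.11 (adjusted p = 0.697; mt-Nd4l led), which median-ratio scaling turned to 0.03.

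Lists of macrophage polarization were not called in the main comparison, and their calls depended on the processing and on single libraries. Alternative activation genes had a median of 0.11 (camera adjusted p = 0.0765), with the lectin gene Clec10a at 76.1 ± 33.1 against 161 ± 26.2 and the arginase gene Arg1 at 62.5 ± 6.82 against 39.6 ± 10.8. Inflammatory cytokines and NF-kB targets had a median of -0.32 (adjusted p = 0.394), with Il6 at 22.6 ± 7.17 against 11.5 ± 4.05, and with the tumour-cell score as a covariate -0.65, called at the preset correlation (adjusted p = 3.60e-07) but not with an estimated correlation (adjusted p = 0.617). Angiogenic, matrix and growth factor genes had a median of -0.25 (adjusted p = 0.104; Hbegf 34.3 ± 11.8 against 13.3 ± 5.99, Adm 5.62 ± 4.22 against 1.44 ± 0.308), and with that covariate -0.33, again called at the preset (adjusted p = 2.21e-05) but not with an estimated correlation (adjusted p = 0.557). They were called without Atg5 WT replicate 2 (median -0.39, adjusted p = 3.47e-05) and Atg5 KO replicate 2 (median -0.51, adjusted p = 0.00435). They were not called without Atg5 KO replicate 1 or 3 (medians -0.12 and -0.13, adjusted p = 0.4053 and 0.1765). The same held without Atg5 WT replicate 1 or 3 (medians -0.25 and -0.17, adjusted p = 0.1253 and 0.9484). Immune checkpoint genes had a median of 0.48 (adjusted p = 0.104), with the ectonucleotidase Nt5e at 6.85 ± 1.36 against 3.02 ± 0.83. Their median was 0.06 without Atg5 WT replicate 2 (adjusted p = 0.698), and they were called without Atg5 WT replicate 1 (0.54, adjusted p = 0.0363) and 3 (0.63, adjusted p = 0.00518). Leaving out Atg5 WT replicate 2 gave the inflammatory list -0.65 (adjusted p = 3.31e-07) and alternative activation -0.32 (adjusted p = 0.151), while leaving out Atg5 WT replicate 3 gave 0.05 (adjusted p = 0.143) and 0.47 (adjusted p = 1.26e-04). The inflammatory list was also called without Atg5 KO replicate 2 (-0.60, adjusted p = 0.00608), and alternative activation without Atg5 WT replicate 1 (0.20, adjusted p = 0.0372) and Atg5 KO replicates 1 and 3 (0.26 and 0.13, adjusted p = 0.0041 and 0.0278). Without the 3 libraries with the most tumour-cell RNA the camera test crossed its threshold for alternative activation in the other direction (-0.38, adjusted p = 0.0052) and for the inflammatory (-0.62) and angiogenic (-0.33) lists. That fit sets a single library labelled Atg5 WT, replicate 3, against 2 labelled Atg5 KO, so these values rest on 1 mouse and are not taken as calls. With all 6 libraries and no covariate, the angiogenic list was called with no filter, median-ratio scaling, quantile normalization and the replicate number as a block (adjusted p = 0.0452, 0.0203, 0.0132 and 0.0451). Alternative activation was called with no filter and the block (adjusted p = 0.0266 and 0.0418), checkpoint genes with the block (adjusted p = 0.0418), and the inflammatory list with quantile normalization and with library weights, whose estimation did not converge (adjusted p = 0.029 and 0.0414). With an estimated correlation in the main comparison, alternative activation, the inflammatory, angiogenic and checkpoint lists had adjusted p = 0.759, 0.9, 0.566 and 0.727.

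Markers of other leukocytes and of handling were not called in the main comparison either. The medians were -1.12 for neutrophils (camera adjusted p = 0.202; Csf3r was higher, 20.1 ± 2.2 against 31.2 ± 6.25), -1.19 for B and plasma cells (adjusted p = 0.295), 0.11 for monocytes (adjusted p = 0.295; Plac8 led) and -0.28 for dendritic cells (adjusted p = 0.927), among which Batf3 was higher. B and plasma cells were called with no filter (median -0.51, adjusted p = 0.00511) and without Atg5 WT replicate 2 (median -1.31, adjusted p = 0.0108), and dendritic cells without Atg5 KO replicate 2 (median -0.58, adjusted p = 0.0441). With an estimated correlation in the main comparison, neutrophils, B and plasma cells and dendritic cells had adjusted p = 0.503, 0.759 and 0.963. Without the 3 libraries with the most tumour-cell RNA, which leaves a single library labelled Atg5 WT, the neutrophil and B cell medians were -0.49 (adjusted p = 0.0177) and -1.91 (adjusted p = 2.58e-07), not taken as calls. On leaving out any 1 library the medians ran from -1.26 to -0.60 for neutrophils, -1.78 to -0.62 for B and plasma cells, -0.07 to 0.51 for monocytes and -0.58 to -0.13 for dendritic cells. The neutrophil median was -0.34 with the tumour-cell score as a covariate, and over all alternatives it ran up to -0.0987. Dissociation and immediate early genes had a median of -0.09 with all 6 libraries, equal to that of all genes (adjusted p = 0.618), with Klf6 at 235 ± 4.76 against 180 ± 12.5. Their median ran from -0.1483 to -0.0443 on leaving out any 1 library. They were called with quantile normalization (median -0.11, adjusted p = 0.0354), but not in the main comparison with an estimated correlation (adjusted p = 0.759). T and NK cells, red cells and platelets, and adipocytes had 4, 4 and 0 genes past the filter and were not tested. The median FPKM of their genes was at most 0.804, 0.541 and 0.16 in any library.

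**Figure D4:**
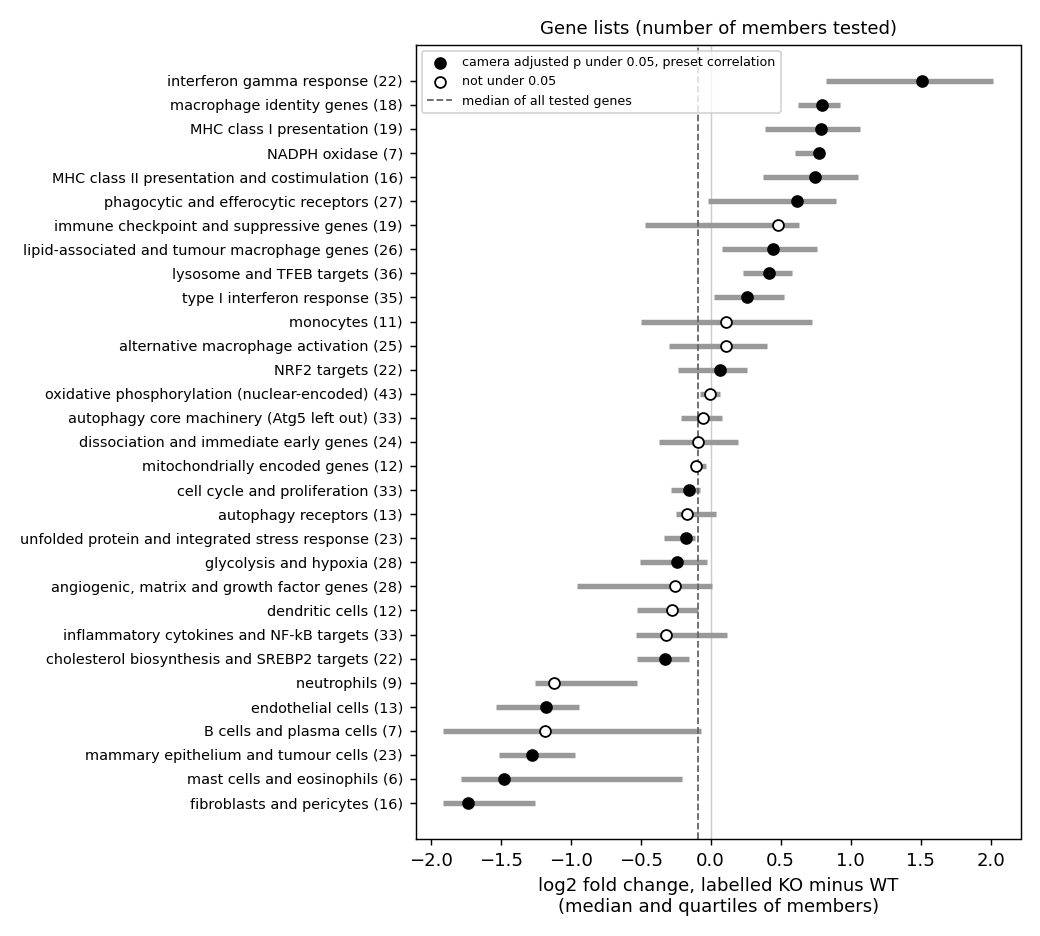
Median (points) and quartiles (bars) of the log2 fold change of each list's members, labelled Atg5 KO minus labelled Atg5 WT, with the number of members in brackets; filled points have a camera adjusted p under 0.05 at the preset correlation, and the dashed line is the median of all tested genes, -0.09. Medians run from -1.73 for fibroblasts and pericytes to 1.51 for the interferon gamma response, and no list was called with an estimated correlation.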

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

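Calls in this series were sensitive to single libraries. The tumour-cell covariate, limma-voom, the fit without 3 libraries and the macrophage list without Lyz2 were chosen after seeing the data. Of the 97 named genes, 97 kept their sign under every alternative run. These genes were chosen for a small p in the same libraries, most with groups that did not overlap. The kept signs were therefore largely fixed by the choice. Of 18 called lists, 16 kept the sign of their median throughout and 11 kept their call on leaving out any 1 library. Pseudocounts, the FPKM filter of 5, quantile normalization, robust empirical Bayes, the log2 fold limit, the covariate and limma-voom left the counts at 0 higher and 1 lower. The count of lower genes was 0 with no filter, with median-ratio scaling and without 3 libraries; the Lyz2 log2 differences were then -8.29, -8.16 and -8.79 (adjusted p = 0.054, 0.123 and 0.0621). More genes were tested with no filter, and fewer libraries entered the last fit, in which the lone library labelled Atg5 WT was assumed to vary like the others; the cause was otherwise not tested. Library weights gave 2033 higher and 3973 lower genes and an Atg5 difference of 1.48 with a call, but their estimation did not converge and gave Atg5 WT replicate 1 a weight of 24002 against at most 0.388 for the others. Leaving out 1 library gave 0 to 2 higher and 0 to 16 lower genes, the highest counts without Atg5 WT replicate 2, 16 to 20 lists, Atg5 differences of 1.39 to 1.54 and Lyz2 differences of -8.77 to -7.93. Over all alternatives the adjusted p ran from 9.19e-05 to 0.37 for Lyz2 and from 0.00186 to 0.906 for Atg5. The number of lists was 0 with the estimated correlation and 15 to 21 in the other fits, the covariate (15) included.

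The replicate numbers name separate mice and are not stated to pair them, so they were not taken as pairs in the main fit. Same-numbered libraries had correlations of 0.21, -0.38 and 0.59 between their deviations from the group means. Not every library correlated best with its own number. These correlations cannot decide on pairing, because the libraries also differed in tumour-cell RNA. With the replicate number as a block, 0 genes were higher and 0 lower, the Lyz2 difference was -8.29 (adjusted p = 0.264) and 21 lists were called; the block leaves 2 residual degrees of freedom.

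Median-ratio scaling and quantile normalization moved the median of all genes by 0.118 and 0.124. Some list medians changed sign. With median-ratio scaling they were 0.126 for oxidative phosphorylation, 0.0467 for dissociation, 0.0303 for mitochondrially encoded and 0.0784 for autophagy core genes, and with quantile normalization 0.0179 and 0.033 for the first and last of these. Library weights gave -0.0744 for alternative activation, 0.0083 for oxidative phosphorylation and -0.0589 for monocytes. With the covariate the medians were 0.0788 for tumour epithelium, -0.292 for alternative activation, 0.0713 for oxidative phosphorylation, -0.083 for monocytes, 0.0927 for mitochondrially encoded and 0.018 for autophagy core genes. Without 3 libraries they were -0.0321 for type I interferon, 0.0308 for tumour epithelium, -0.378 for alternative activation, past the threshold in the other direction but from 1 library labelled Atg5 WT, -0.0807 for checkpoint genes, 0.089 for oxidative phosphorylation, -0.044 for monocytes, 0.175 for mitochondrially encoded and 0.0393 for autophagy core genes. Leaving out 1 library gave -0.323 to 0.473 for alternative activation, -0.0465 to 0.0455 for oxidative phosphorylation, -0.0688 to 0.512 for monocytes, -0.254 to 0.0429 for mitochondrially encoded genes and -0.645 to 0.0514 for inflammatory genes. The cause of these sign changes was not tested. At the measured spread the simulated test called 25.3% of log2 changes of 1. The simulated genes varied independently, so that share need not hold in the real libraries.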

Other observations

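Some genes outside the fixed rule stood out in the libraries labelled Atg5 KO and were chosen after their values were seen. Cxcl13, which encodes a B cell chemokine, had an FPKM of 4.21 ± 3.64 against 32.8 ± 11.4, and Cd5l, a secreted macrophage protein, 5.54 ± 3.20 against 29.5 ± 15.5, giving the libraries labelled Atg5 WT first. Both had groups that did not overlap, and neither passed over all genes (limma-trend adjusted p = 0.492 for each). The interferon gamma gene Ifng had an FPKM of at most 0.172 in any library, and Cd3e, a T cell gene, at most 0.577.

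The patterns weighed below all took their directions from labels that gene-level Atg5 goes against and Lyz2 goes with. The tests of exchanged labels, of macrophage or tumour-cell share by the covariate, and of Lyz2 reads counted to Lyz1 were chosen after the results were seen. The tests of neighbouring genes, of the list score less the macrophage score, of a single library and of other splits were written before.

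Gene-level Atg5 was higher, not lower, in the libraries labelled Atg5 KO. An exchange of the labels is argued against by Lyz2, which would then be lost in mice without the knock-in (log2 difference -8.29, SE 0.47). The 1.39 (SE 0.11) with the tumour-cell score as a covariate cannot decide on a larger macrophage share, since the covariate measures tumour-cell RNA. Atg5 stayed between 5.11 and 5.28 FPKM over the libraries labelled Atg5 WT. Their macrophage scores without Lyz2 ran from 6.555 to 8.264. These values argue against a larger macrophage share, if the macrophage score follows the share. An effect on the region is argued against by a median of -0.13 over 17 tested genes within 2 Mb. What stays open is a change in the amount or stability of transcripts from the recombined allele, a hypothesis that values per exon could test and that values per gene did not.

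Lyz1 was 8.55-fold higher where Lyz2 was 367-fold lower. Lyz2 reads counted to Lyz1 would make Lyz1 fall with its source, so they cannot make its rise of 3.16 (SE 0.35). That rise is the pattern itself and no separate test. Lyz1 stood at 3.64% to 4.83% of Lyz2 in the libraries labelled Atg5 WT and above it in those labelled Atg5 KO. Such reads may make up part of the Lyz1 value in the libraries labelled Atg5 WT, so the 8.55-fold is uncertain. The 2.77 (SE 0.21) with the covariate cannot decide on a larger macrophage share, since the covariate measures tumour-cell RNA. In the libraries labelled Atg5 WT, Lyz1 rose with the macrophage score without Lyz2, from 99.5 FPKM at 6.555 to 239 at 8.264. Atg5 KO replicates 1 and 2, at 8.132 and 8.255 within that range, had 1197 and 1761 FPKM, and replicate 3 had 1554 at 8.463. These values argue against a larger share as the whole cause, if that score follows the share. An effect on the whole region is argued against by a median of -0.18 over 21 tested neighbours within 2 Mb. A response of Lyz1 to the loss of Lyz2, or a local effect of the knock-in on the adjacent gene, may account for it. The series holds only the 2 groups compared here. It has no group with LysMcre but without Atg5 flox alleles, which would separate these explanations from an effect of Atg5.

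The interferon gamma list was higher in the libraries labelled Atg5 KO, with a median of 1.51. With the covariate the median was 1.32, so the tumour-cell score left most of it in place. The standard error of the members' mean, 0.204, treats genes that vary together as independent and holds no spread between mice. With the covariate and an estimated correlation camera did not call the list (adjusted p = 0.557). Less tumour-cell RNA as the whole cause is therefore not decided. A single library is argued against by a lowest median of 1.28 when any 1 was left out. The same 1.32 cannot decide on a larger macrophage share. The covariate measures tumour-cell RNA, and it brought the macrophage identity median from 0.79 only to 0.36. Over the libraries labelled Atg5 WT the list's mean ran from 2.50 to 3.07 while the macrophage score without Lyz2 ran from 6.555 to 8.264. Atg5 KO replicates 1 and 2, at scores of 8.132 and 8.255 within that range, had list means of 4.59 and 3.51. Replicate 3 had 4.73 at 8.463. These values, looked at after the results were seen, argue against a larger macrophage share as the whole cause, if that score follows the share. A part of the pattern may still come from it. In the test written before, the list's score less the macrophage score without Lyz2 was higher by 0.65. That was under 2 standard errors (0.505 each, exact permutation p = 0.3). A response of the macrophages to targeting of Atg5 or to loss of Lyz2 may also account for the pattern, which the design does not separate. Of the 25 interferon gamma genes 6 are also in another list, and of the 23 tumour-cell genes 0.

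The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1 gene and the highest of the others 0, and 1 split, the real one, gave as many. For the lists the real split called 18 and the highest of the others 21, with 5 splits giving as many or more. The split of Atg5 WT replicates 1 and 2 and Atg5 KO replicate 1 from the rest, the 3 libraries with the most tumour-cell RNA, had 3544 genes at an unadjusted p under 0.05 against 1235 in the real split, which points to a structure of the libraries by tumour-cell RNA. The median of the interferon gamma list was 1.51 in size in the real split and at most 1.13 in the others. At the preset correlation camera called that list in 7 of the other splits, MHC class I in 6 and mast cells in 1. The MHC class II, lysosome, macrophage identity, lipid-associated and phagocytic lists were each called in 9. A call at the preset correlation therefore does not by itself tell the labels from other groupings of the libraries.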
